A study of Mus musculus with 8 samples.

How the data were processed

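RNA-seq was made from the mouse fusion-negative rhabdomyosarcoma cell line KMR46 after 60 h with lipofectamine alone (4 libraries) or with miR-449a and miR-340 (4 libraries). Per the labels' protocols, polyadenylated RNA was made into stranded TruSeq libraries and sequenced on a HiSeq4000. The authors deposited 1 table of raw read counts per gene symbol, with 18877 genes and no normalization. Per the submitters' processing notes, the tools were TopHat2 2.0.13, SAMtools 0.1.19.24, HTSeq 0.5.3p3 and DESeq2, with genome build mm10. The role of each tool, the strand setting of the counting, the annotation release and the parameters are not given in the sources used here. Every gene in the table had at least 2 counts over the 8 libraries. Libraries were assigned to groups by the treatment label, and every column of the table matched a library by its description label.

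Counts were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, 2-sided, with TMM factors (0.9765 to 1.0198), genes filtered by filterByExpr on the group and robust dispersion estimates. The 11023 genes tested held at least 99.42% of the counts of each library. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called at a value under 0.05. CPM values are counts scaled by edgeR to the TMM-adjusted library size, and SDs are over the 4 libraries of a group. Log2 fold changes are transfected over vehicle, with edgeR's prior count of 0.125, and so understate changes of genes at a few counts. With 2405517 to 5963473 counts per library, a count of 0 allows up to 0.52 to 1.26 CPM (3 counts), which covers counting error only. Pairs of libraries of a group differed by 2.50 to 14.88 times the sampling noise (chi-square per degree of freedom), so none was counted as a repeat of another.

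Before the data were examined, 40 gene lists were fixed from general knowledge, of pathways, quality signs, reported microRNA targets and markers of other cell types, and 1153 of their 1238 entries were in the table. Lists with at least 5 tested members (35) were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The numbers of members called are given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, no overlap between groups and no predicted-gene symbol. It adds 16 fixed genes, up to 4 members of each described list by p in the direction most moved with 1 that moved against it, and the 5 largest falls with a site for each microRNA.

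Gene symbols were matched to GENCODE release M21 on GRCm38, the assembly of mm10, by name (17607) or with older symbols (18140 in all). The longest 3' UTR of at least 30 bases was used per gene. Log2 fold changes were regressed on the presence of a match to bases 2 to 8 of each microRNA, with log10 UTR length and GC content as covariates. The coefficient was ranked among those of all heptamers present in 5% to 60% of the 3' UTRs, and the share of heptamers with a coefficient as low was taken as a 1-sided empirical measure with a threshold of 0.05. Coordinates are 1-based. Sequence work, permutations and summaries used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

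The procedure was tested on simulated counts for this comparison, drawn from the vehicle means and the library sizes over 11023 genes. At a 1.5-fold change 52.2% of 67 genes were recovered, at 2-fold 88.1% of 67 and at 4-fold 98.5% of 66. Of 167 genes called, 8 (4.8%) had not been changed and 0 had the wrong sign. The genes changed in the simulation were far fewer than the 5283 called in the data. Recovery and false calls with that many changed genes were therefore not tested. In simulated lists of 30 genes, the 1 raised list was called and 0 of the 19 others were. The simulated genes were drawn independently, so false calls of lists whose genes are correlated were not tested. For the seed matches, log2 fold changes of 10234 genes were drawn at random and independently, not from counts. A shift of -0.3 planted in them at 1 heptamer was recovered as -0.301 at rank 1, and smaller shifts were not tried.

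The alternatives were DESeq2 size factors and upper-quartile factors in edgeR, no filter and a filter of at least 1 CPM in 4 libraries or more, planned as stricter but keeping 12996 genes against 11023, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn. For seed matches they were shorter and longer matches, no covariates, the shortest UTR, the coding sequence and genes of at least 5 CPM. An alternative without Yam1 and the mitochondrially encoded genes was added after the data were examined. DESeq2 gave no adjusted p for 4759 genes, which were left as missing. No column of per-sample values was left out.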

Results

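Bulk RNA-seq was performed on KMR46, a cell line from murine fusion-negative rhabdomyosarcoma, a soft-tissue tumour of cells that resemble skeletal muscle precursors and carry no PAX-FOXO1 fusion gene. According to the labels, the line has a MyoD-Cre driver, a floxed p53 allele and an oncogenic KRas allele. Cells received lipofectamine alone (vehicle, 4 libraries) or lipofectamine with miR-449a and miR-340 together (4 libraries), and RNA was taken at 60 h. The comparison asks which transcripts differ after the 2 microRNAs were introduced into these tumour cells. The series' title speaks of cell identity, so genes of the muscle programme were among those fixed in advance. No library with a control RNA and no library with a single microRNA was analysed here, so the effect of either microRNA alone, and that of transfected RNA as such, is part of the same contrast. The count table held 18877 genes. Total counts ran from 2405517 (transfected replicate 1) to 5963473 (transfected replicate 3), and the other libraries had 3879783, 2462371, 3734003 and 4182601 (vehicle replicates 1 to 4) and 2592179 and 2926898 (transfected replicates 2 and 4).

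The first principal component of log2 CPM carried 65.4% of the variance and separated the groups, with the vehicle libraries between -40.8 and -35.65 and the transfected libraries between 36.41 and 39.72. The second, with 11% of the variance, set transfected replicate 4 (-36.86) apart from the other 3 transfected libraries (7.46 to 21.49). In this library 4.06% of the counts belonged to Yam1, a transcript with no match in the reference annotation, against 6.64% to 7.77% in the other 7 libraries, and mitochondrially encoded genes took 6.35% against 7.49% to 9.43%. The protein-coding mitochondrial genes alone took 3.95% in it, within the 3.5% to 4.79% of the other 7 libraries. Pearson correlations of log2 CPM across genes were 0.978 to 0.985 within vehicle, 0.957 to 0.981 within the transfected group and 0.899 to 0.921 between groups. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

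**Figure D1:**
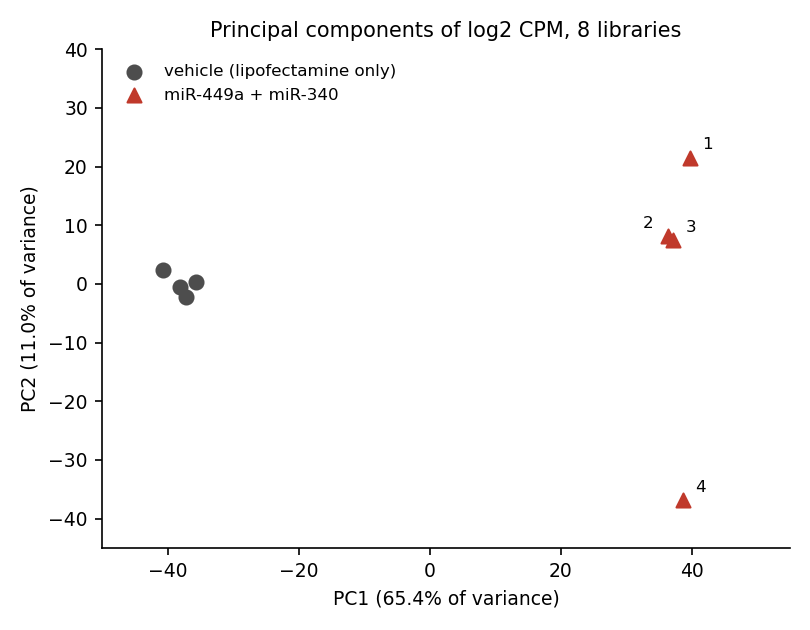
Principal components of log2 CPM, with component 1 (65.4% of the variance) on the x axis and component 2 (11% of the variance) on the y axis. Grey circles are the 4 vehicle libraries and red triangles the 4 transfected libraries, marked with their replicate number; the groups lie apart on component 1, and transfected replicate 4 lies at -36.86 on component 2.

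After transfection, Penk, which encodes the precursor of the enkephalin peptides, fell from 802.5 ± 51.3 to 39.7 ± 12.7 CPM (SD, n = 4 in each group), a 20.2-fold drop with log2 fold change -4.34 (SE 0.16, edgeR adjusted p = 3.69e-13). Crabp1, a cytoplasmic retinoic acid-binding protein gene, fell from 2679 ± 419 to 182 ± 71.0 CPM (log2 fold change -3.88, SE 0.32, edgeR adjusted p = 2.60e-05). In the other direction Ctgf, which encodes a matricellular growth factor, rose from 5.67 ± 2.94 to 182 ± 28.7 CPM (log2 fold change 4.94, SE 0.21, edgeR adjusted p = 2.75e-12). Ankrd1, a stretch-responsive ankyrin repeat gene of striated muscle, rose from 31.8 ± 4.13 to 391.5 ± 68.2 CPM (log2 fold change 3.63, SE 0.13, edgeR adjusted p = 2.63e-15).

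The other genes with the largest falls were Kcnk3, a potassium channel gene that went from 181 counts in the 4 vehicle libraries to 4 counts in the 4 transfected libraries (log2 fold change -5.29, SE 0.46), Scara5 (-4.22), Npr3 (-4.20), Dpt (-4.07), Msx3 (-4.01) and Papss2 (-3.68). Those with the largest rises were Saa3, an acute-phase serum amyloid gene that went from 4 to 340 counts over the 4 libraries of each group (log2 fold change 6.34, SE 0.46), Serpind1 (4.98), the 5-lipoxygenase gene Alox5 (3.94), the cardiac sodium channel gene Scn5a (3.69), Plscr2 (3.17) and Iqcd (3.11). In each of these 16 genes the 4 transfected libraries did not overlap the 4 vehicle libraries, and the adjusted p of the edgeR quasi-likelihood test was at most 2.60e-05.

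Over all 11023 genes tested, 5283 (47.9%) changed at an edgeR quasi-likelihood FDR under 0.05, 2649 of them higher and 2634 lower after transfection. The median size of the log2 fold change among them was 0.74. At least 2-fold changes were fewer and mostly downward, with 552 genes higher and 1044 lower (1596 in all). The 2 groups did not overlap in 42.3% of tested genes, where chance gives 2.86%, and 4387 of the changed genes were among these. DESeq2 called 5103 genes, of which 4772 were also called by edgeR. Without transfected replicate 4, 5845 genes changed, and 5019 of them were among the 5283.

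Several genes reported elsewhere as targets of the miR-34 and miR-449 families were fixed in advance and were lower. Notch1, which encodes a transmembrane receptor, fell 12.5-fold from 16.96 ± 2.13 to 1.38 ± 0.44 CPM (log2 fold change -3.64, SE 0.30, edgeR adjusted p = 8.29e-10). The receptor tyrosine kinase gene Met fell from 95.8 ± 7.38 to 40.3 ± 7.03 CPM (log2 fold change -1.23, SE 0.13). E2f5, a transcription factor gene of the E2F family, fell from 25.3 ± 4.91 to 9.81 ± 3.74 CPM (-1.27, SE 0.22), and the cyclin E gene Ccne2 from 22.0 ± 3.86 to 9.41 ± 1.99 CPM (-1.22, SE 0.20). Ccnd1, the cyclin D1 gene, fell from 2148 ± 135.5 to 1251 ± 145 CPM (-0.78, SE 0.10) and Cdk6, a kinase partner of D-type cyclins, from 64.8 ± 5.83 to 45.5 ± 5.67 CPM (-0.51, SE 0.12). Cdk4, the other such kinase, was higher, at 289 ± 32.1 against 221 ± 22.0 CPM (0.39, SE 0.10, edgeR adjusted p = 0.0027). The antigen Ki-67 gene Mki67, a proliferation marker, fell from 69.2 ± 5.11 to 12.1 ± 4.84 CPM (-2.48, SE 0.20, edgeR adjusted p = 1.57e-09). Kras (log2 fold change -0.15, SE 0.10, edgeR adjusted p = 0.2212), the cyclin-dependent kinase inhibitor gene Cdkn1a (0.25, SE 0.12, 0.0829) and the mitochondrial pyruvate carrier gene Mpc2 (0.14, SE 0.14, 0.4202) did not pass the test. Mpc1, its partner, had 5 to 12 counts per library and was not tested.

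Of the fixed genes of the muscle programme, the embryonic myosin heavy chain gene Myh3 rose from 1.72 ± 0.70 to 5.97 ± 2.36 CPM (log2 fold change 1.64, SE 0.40, edgeR adjusted p = 0.0017). Myog, which encodes the differentiation factor myogenin, rose from 2.28 ± 1.31 to 5.71 ± 2.82 CPM (1.19, SE 0.42, edgeR adjusted p = 0.024), with overlapping libraries. Its call was lost without transfected replicate 4 (log2 fold change 0.79), without vehicle replicate 2 (0.98) and without vehicle replicate 3 (1.03). The lineage factor gene Myod1 was at 3.15 ± 1.18 CPM in vehicle and 4.24 ± 1.46 CPM after transfection and did not pass the test (0.46, SE 0.38, edgeR adjusted p = 0.3379). Pax7 was not in the count table and could not be tested.

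**Figure D2:**
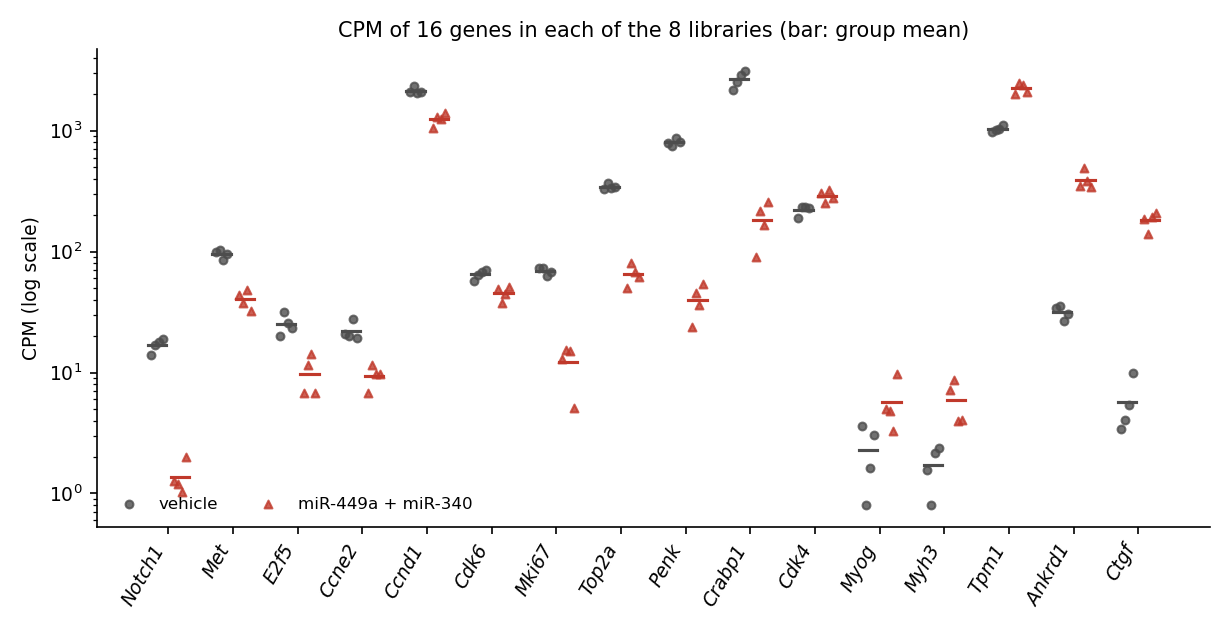
CPM (log scale, y axis) of 16 genes (x axis) in each library. Grey circles are the 4 vehicle libraries, red triangles the 4 transfected libraries, and horizontal bars the group means; Notch1, Penk and Crabp1 are lower in all 4 transfected libraries, Ctgf and Ankrd1 are higher in all 4, and the libraries of the 2 groups overlap for Myog.

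Of 56 tested cell cycle genes of G2/M and mitosis, 54 fell and 0 rose, with a median log2 fold change of -1.66 (limma camera adjusted p = 1.35e-22, and adjusted p = 0.0369 with an estimated correlation). The DNA topoisomerase gene Top2a fell from 344 ± 16.7 to 65.0 ± 12.3 CPM, and the kinetochore genes Cenpf (log2 fold change -2.42) and Cenpe (-2.20) and the spindle gene Nusap1 (-2.22) fell too. The securin gene Pttg1 did not pass the test (log2 fold change 0.16, SE 0.14). Among 42 genes of DNA replication 24 fell and 0 rose (1 rose without transfected replicate 3, median -0.47, camera adjusted p = 1.89e-05, and adjusted p = 0.0369 with an estimated correlation). Examples were Mcm5 (log2 fold change -2.58) and Mcm3 (-1.25) of the replicative helicase, the ribonucleotide reductase gene Rrm1 (-1.20) and the thymidine kinase gene Tk1 (-1.70). Of 22 G1/S regulators 14 fell, among them Ccnd3 (-1.54), Cks1b (-1.16) and E2f2 (-2.40), and 1, Cdk4, rose (median -0.76, camera adjusted p = 2.83e-04), a call that was lost with an estimated correlation (adjusted p = 0.1092 with an estimated correlation). Adjusted over the list alone, the numbers that fell were 54, 24 and 15.

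Contractile apparatus genes that could be tested were higher as a group, with 11 of 22 tested members up and 3 down (1 down without transfected replicate 1, vehicle replicate 1 or vehicle replicate 2, median log2 fold change 0.69, camera adjusted p = 0.012). Of the 56 genes listed, 46 were in the count table and 22 passed the filter, so the result describes part of the list. Its summed CPM went from 1818 ± 92 to 3073 ± 295, most of it from Tpm1. The call was lost with an estimated correlation (adjusted p = 0.1855 with an estimated correlation), and adjusted over the list alone, 12 rose and 3 fell. Tpm1, a tropomyosin gene, rose from 1039 ± 60.3 to 2235 ± 230 CPM, the intermediate filament gene Des from 2.20 ± 0.48 to 7.84 ± 1.73 CPM, the cardiac troponin T gene Tnnt2 from 5.02 ± 0.92 to 12.4 ± 0.40 CPM and the nebulin gene Neb from 14.2 ± 4.67 to 29.4 ± 6.54 CPM. Eno3, the muscle enolase gene, fell from 34.5 ± 2.61 to 8.42 ± 3.05 CPM. The myogenic regulators were not called (1 higher and 5 lower of 14, 0 higher without vehicle replicate 2 or 3, the same adjusted over the list alone, median -0.22, camera adjusted p = 0.3753). The members that fell included Id3 (-1.47) and Id1 (-1.52), which encode inhibitors of E-protein transcription factors, and Tcf12 (-0.79) and Tcf3 (-0.38), which encode E-proteins, and Myog was the member that rose. Genes of myoblast fusion and early differentiation were not called either (8 higher and 4 lower of 16, 9 and 5 adjusted over the list alone, 9 higher and 7 lower of 18 without transfected replicate 4, camera adjusted p = 0.4842). Within this list the acetylcholine receptor subunit genes moved apart, with Chrna1 (1.09) and Chrng (0.93) higher and Chrnd (-1.02) lower, and the M-cadherin gene Cdh15 rose by a log2 fold change of 1.95.

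Genes of energy metabolism went in both directions. Of 23 glycolysis genes 13 fell and 3 rose, the same numbers adjusted over the list alone (median log2 fold change -0.57, camera adjusted p = 0.0045, and adjusted p = 0.3392 with an estimated correlation). Ldha, the lactate dehydrogenase A gene, fell from 364 ± 15.3 to 116 ± 9.57 CPM, Aldoa from 833 ± 30.3 to 276 ± 25.1 CPM and Tpi1 from 241 ± 9.69 to 117 ± 5.23 CPM, as did the lactate transporter gene Slc16a1 (-1.14), while the glucose transporter gene Slc2a1 rose from 191 ± 17.04 to 344 ± 41.2 CPM. Nuclear genes of oxidative phosphorylation were higher, with 36 of 67 up and 4 down, 38 and 4 adjusted over the list alone (2 down without transfected replicate 1 or vehicle replicate 2, median 0.30, camera adjusted p = 2.55e-04, and adjusted p = 0.3392 with an estimated correlation). Ndufa7 (1.06), Ndufb3 (0.83), Uqcrq (0.66) and Atp5f1 (0.66) rose, and Ndufa8 (-0.81) fell. Among the 37 genes of pyruvate entry and the tricarboxylic acid cycle 12 fell, among them Got2 (-0.93) and Idh3g (-1.17), and 6 rose, among them Mdh2 (0.50), with the same numbers adjusted over the list alone and no call (camera adjusted p = 0.6123). Mitochondrially encoded genes were not called (1 higher and 1 lower of 15). Their numbers were 6 higher and 1 lower without transfected replicate 4, 5 and 1 without vehicle replicate 1, and 1 and 0 without vehicle replicate 3.

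Fibroblast markers were the list with the lowest median, -2.07, with 9 of 11 lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 2.22e-04, and adjusted p = 0.1092 with an estimated correlation). Col3a1, a fibrillar collagen gene, fell from 3062 ± 492.5 to 731.5 ± 62.1 CPM, Fbln1 from 51.8 ± 4.18 to 12.5 ± 2.43 CPM and the PDGF receptor gene Pdgfrb by a log2 fold change of -2.86, while Fbln2 (0.57) rose. Across the wider list of mesenchymal and extracellular matrix genes 20 of 46 fell and 10 rose, 21 and 10 adjusted over the list alone (median -0.21, camera adjusted p = 0.0315, and adjusted p = 0.6427 with an estimated correlation). Timp3 (-1.68), Twist2 (-1.81) and Tgfbi (-1.43) fell and the tenascin C gene Tnc rose from 98.2 ± 7.83 to 281 ± 25.1 CPM. The call of this list was lost without transfected replicate 1 (camera adjusted p = 0.0630). Of 8 tested neuronal markers 7 fell and 0 rose, the same adjusted over the list alone (median -1.57, camera adjusted p = 5.53e-05, and adjusted p = 0.0369 with an estimated correlation). The neurofilament gene Nefl fell from 1528 ± 78.9 to 340 ± 16.5 CPM, Gap43 from 477 ± 37.3 to 238 ± 27.0 CPM, Stmn2 from 62.7 ± 8.81 to 15.5 ± 2.78 CPM and Snap25 from 16.1 ± 3.44 to 1.34 ± 0.998 CPM.

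Inflammatory cytokines were higher, with 12 of 18 up and 3 down, the same adjusted over the list alone (median 0.83, camera adjusted p = 0.007, and adjusted p = 0.1855 with an estimated correlation). The chemokine genes Cxcl1, Ccl2 and Ccl7 rose from 16.2 ± 1.92 to 98.01 ± 20.3 CPM, from 42.7 ± 6.04 to 133 ± 34.7 CPM and from 71.3 ± 8.92 to 139 ± 17.8 CPM. The plasminogen activator inhibitor gene Serpine1 rose by a log2 fold change of 1.54, and Igfbp3, which encodes a binding protein of insulin-like growth factors, fell (-2.44). The interferon response list was not called (6 higher and 4 lower of 24, the same adjusted over the list alone, median 0.12, mean -0.05, camera adjusted p = 0.8091), with Rsad2 (1.37), B2m (0.80), Bst2 (1.44) and Eif2ak2 (0.81) higher and Isg20 (-2.76) lower. Macrophage markers summed to 75.7 ± 6.50 CPM in vehicle and 91.8 ± 15.1 CPM after transfection (2-sided exact permutation p = 0.1143), and their list was not called (2 higher and 0 lower of 9, 0 and 0 adjusted over the list alone). Those 2, C1qa (2.41 CPM in vehicle, log2 fold change 0.89) and Mrc1 (3.27 CPM, 0.82), lost their calls in most alternatives, so that 1 was called without transfected replicate 2 or vehicle replicate 1, and 0 without transfected replicates 1 or 3 or vehicle replicates 2, 3 or 4. Without transfected replicate 4, 3 of 10 markers were called higher, C1qa with Cd68 and Lyz2. Ribosomal protein genes were slightly lower, with 30 of 75 down and 1 up, 28 and 1 adjusted over the list alone (median -0.23, camera adjusted p = 2.22e-04, and adjusted p = 0.3392 with an estimated correlation). Rpl31 (-0.93), Rps2 (-0.87), Rpl18a (-1.23) and Rps19 (-0.66) fell. Rpl27 was the member called higher (0.26), and lost that call without transfected replicate 4 (0.145), without any 1 of the 4 vehicle libraries (0.225 to 0.283) and without Yam1 and the mitochondrially encoded genes (0.235). Reads of these genes can be shared with their many processed pseudogenes, so single values in this family are uncertain.

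**Figure D3:**
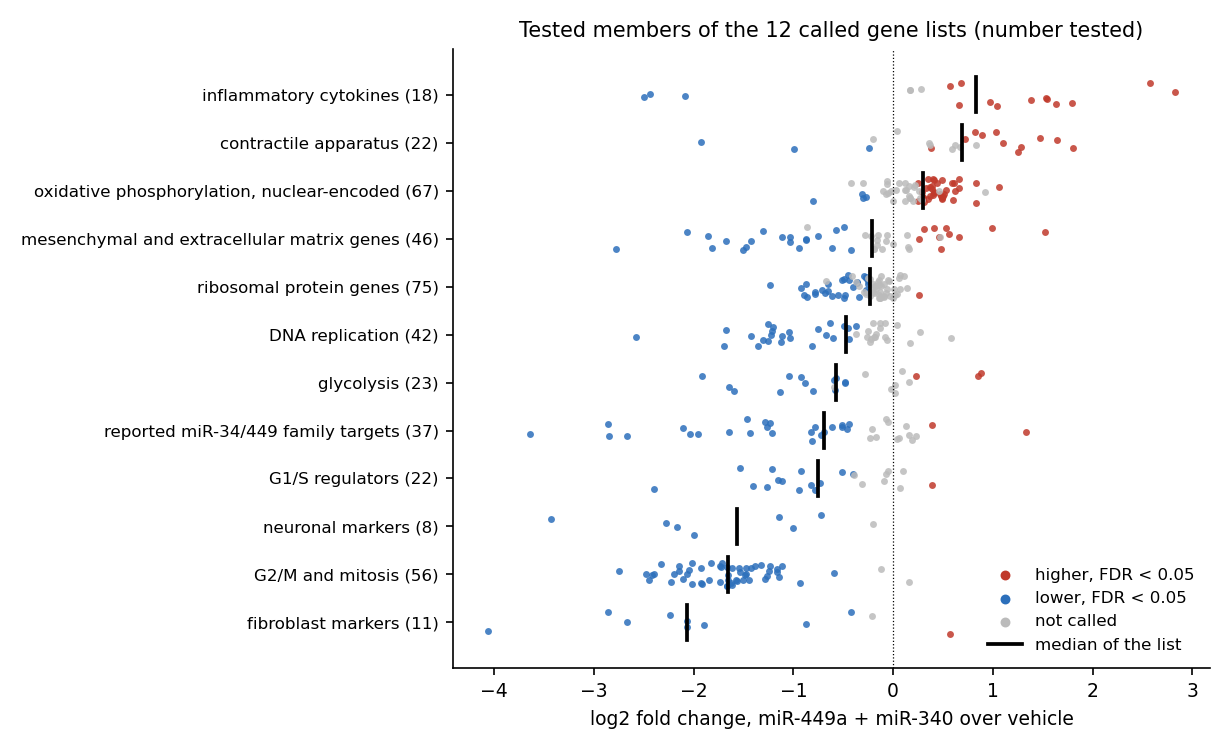
Log2 fold change (x axis) of each tested member of the 12 called gene lists (y axis, number tested in brackets). Red and blue points are members called higher and lower by edgeR, grey points were not called, and the black bar is the list's median; the medians run from -2.07 for fibroblast markers to 0.83 for inflammatory cytokines, and 54 of the 56 genes of G2/M and mitosis are called lower.

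Genes reported elsewhere as targets of the miR-34 and miR-449 families were lower as a list, with 24 of 37 down and 2 up, 25 and 2 adjusted over the list alone (median -0.69, camera adjusted p = 1.89e-05, and adjusted p = 0.0369 with an estimated correlation). Beside Notch1 and Ldha they included the growth arrest gene Gas1, from 114 ± 17.4 to 15.9 ± 4.49 CPM, Arhgap1, from 68.7 ± 6.23 to 16.3 ± 3.84 CPM, and Rras, from 85.8 ± 10.7 to 21.7 ± 5.28 CPM. Ccp110, which encodes a centriole cap protein, rose from 3.89 ± 0.70 to 9.74 ± 2.46 CPM. This list shares 7 tested genes with the G1/S regulators. Genes reported as miR-340-5p targets were not called (12 lower and 4 higher of 28, the same adjusted over the list alone, median -0.28, camera adjusted p = 0.0724), and Notch1, Met, Ccnd1 and Cdk6 stand in both target lists. Sox2 (-1.14) and the Polycomb methyltransferase gene Ezh2 (-1.01) fell and Jak1 (0.63) rose. The Notch pathway list was not called (6 lower and 3 higher of 18, 7 and 3 adjusted over the list alone, camera adjusted p = 0.6123). Its members Numbl (-1.84), Rbpj (-0.73) and Dll1 (-1.47) fell with Notch1, and the presenilin gene Psen1 (1.08) rose.

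None of the remaining lists with at least 5 tested members was called. YAP/TAZ target genes had 10 higher and 7 lower of 25, with Cyr61 (2.25) rising beside Ctgf and Ankrd1, and a median (-0.05) and mean (0.25) of opposite sign. Chromatin remodellers and Polycomb genes had 15 lower and 5 higher of 38 (2 higher without vehicle replicate 1, 3 without vehicle replicate 3 or 4, camera adjusted p = 0.1406), among them Smarca2 (-1.48), Pbrm1 (-0.94) and Kdm6a (-1.12) lower and Hdac4 (0.55) higher. The p53 target genes had 10 higher and 9 lower of 33 (11 and 10 adjusted over the list alone), with Plk2 (1.69) and Fbxw7 (1.08) higher and Trp53inp2 (-0.80) lower. RAS-MAPK and PI3K pathway components had 11 higher and 8 lower of 35 (median 0.14, mean -0.12), with Pten (0.52) higher and Pdgfrb lower, and RAS-MAPK output genes 8 higher and 8 lower of 30. Satellite cell and progenitor genes had 6 higher and 6 lower of 15 (6 and 7 adjusted over the list alone). The cyclin-dependent kinase inhibitors and quiescence genes had 3 higher and 5 lower of 20 (median 0.04, mean -0.19), apoptosis regulators 8 and 3 of 24 (median -0.02, mean 0.13), and fatty acid oxidation 5 and 3 of 27 (6 and 6 without transfected replicate 4, median -0.07, mean 0.03). Cholesterol biosynthesis had 5 higher and 6 lower of 24, the unfolded protein and integrated stress response 12 and 8 of 33, the WNT pathway 3 and 5 of 20, and heat shock and immediate early genes 7 and 5 of 20 (median 0.07, mean -0.09). Smooth muscle and pericyte markers had 3 higher and 2 lower of 7, with Tagln (2.34) and Acta2 (1.15) rising and Cspg4 (-2.46) falling, and chondrocyte and osteoblast markers 1 higher and 2 lower of 8 (2 and 2 without transfected replicate 4, median 0.08, mean -0.16). Unless given, these numbers were the same adjusted over the list alone. Fewer than 5 members were tested of the multiciliated cell programme (2 higher and 0 lower of 4), endothelial markers (0 and 2 of 3), epithelial markers (0 and 1 of 2, 0 and 2 of 3 without vehicle replicate 4 or any of transfected replicates 1 to 3), adipocyte markers (2 and 1 of 4, 1 and 1 without vehicle replicate 4, median 0.36, mean -0.05) and B and T lymphocyte markers, which summed to 1.41 ± 1.15 CPM in vehicle and 0.36 ± 0.48 CPM after transfection with no member tested.

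Matches to the microRNA seeds were searched in the longest annotated 3' UTR of 10234 tested genes. The 1818 genes with at least 1 match to bases 2 to 8 of miR-449a (CACTGCC) were lower than the other genes by 0.28 on the log2 scale at equal UTR length and GC content (coefficient -0.279, SE 0.021). Among 10756 heptamers this was the second lowest coefficient, so that a share of 1.86e-04 of them lay as low, after ACTGCCA (-0.295), which is the match to bases 2 to 7 of the same microRNA with an A opposite base 1. For miR-340-5p (CTTTATA, 1622 genes) the coefficient was -0.027 (SE 0.022), at rank 941, and a share of 0.0875 of the heptamers lay as low, which did not pass the threshold of 0.05. Of the other matches to miR-340-5p, TTTATAA (bases 2 to 7 with an A opposite base 1) had -0.022 (rank 1268) and GCTTTAT (bases 3 to 9) -0.006 (rank 2763). The genes are not independent replicates, and the SE is over genes. Genes with only miR-449a matches had a median log2 fold change of -0.22 and 38.5% of the 1409 fell. Genes with only miR-340-5p matches had a median of -0.03 and 26.4% of the 1213 fell. With no match to either, the median was 0.06 and 21.1% of 7203 fell, and with matches to both it was -0.16 and 35% of 409 fell. In the 344 genes with 2 or more miR-449a matches the median was -0.36 and 47.1% fell. For miR-340-5p the median was -0.075 with 1 match (29.8% of 1312 fell) and -0.024 with 2 or more (23.2% of 310). These medians and shares are not adjusted for UTR length. The median length was 917 bases with no match, 2026 with miR-449a only, 2364 with miR-340-5p only and 3772 with both. It was 3171 with 2 or more miR-449a matches. With the shorter match to bases 2 to 7, the miR-340-5p coefficient was -0.057 and passed the threshold, with a share of 0.0102 of the hexamers as low. Hexamers were ranked without the upper limit of 60%. The longer 8mer match gave -0.032, with a share of 0.1754 of the octamers as low. No miR-340-5p setting other than the hexamer passed.

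**Figure D4:**
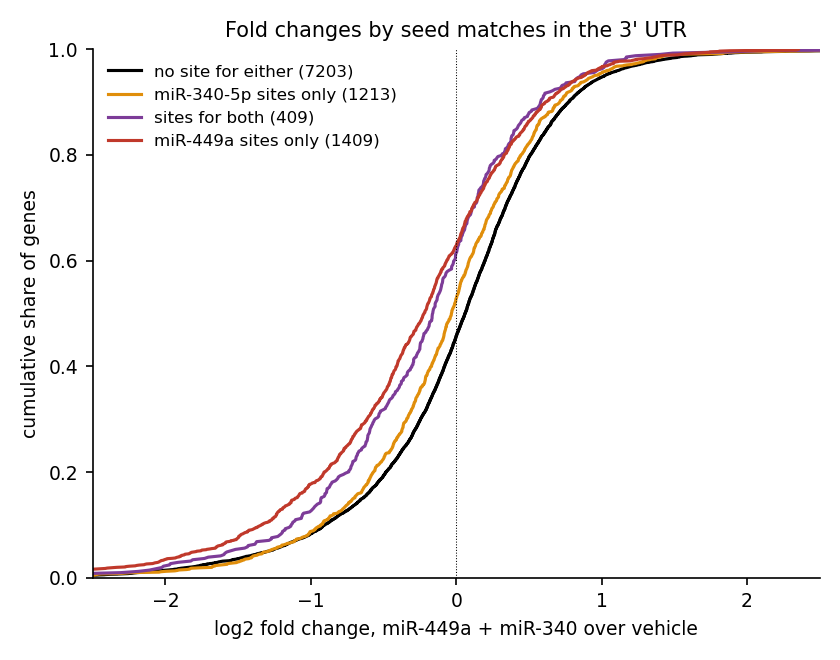
Cumulative share of genes (y axis) by log2 fold change (x axis) for genes with no seed match (black, 7203 genes), miR-340-5p matches only (orange, 1213), matches to both (purple, 409) and miR-449a matches only (red, 1409) in the 3' UTR. The red curve lies left of the black one, with medians of -0.22 and 0.06, and the curves are not adjusted for UTR length.

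In GRCm38 (mm10), Notch1 lies on the minus strand of chromosome 2 (26457903 to 26516663), and its 3' UTR of 1628 bases holds 3 miR-449a matches, at 26459338 to 26459344, 26459067 to 26459073 and 26458725 to 26458731. The first stands in the transcript context TCCACAGAAACACTGCCTTTTTATTTA. Met (chromosome 6, plus strand) has 2 matches, at 17571900 to 17571906 and 17573875 to 17573881, E2f5 (chromosome 3) has 1 at 14606090 to 14606096, and Cdk6 (chromosome 5) has 4 in a 3' UTR of 10217 bases. Ccne2 (chromosome 4) has 1 match to miR-449a, at 11203194 to 11203200, and 1 to miR-340-5p, at 11203882 to 11203888. Kras (chromosome 6, minus strand), which did not pass the test, also has 1 of each, at 145219032 to 145219038 and 145218234 to 145218240. No match to miR-449a was found in the 3' UTRs of Ccnd1, Cdk4 and Mki67. The 5 largest falls with a miR-449a match were those of Kcnk3 (2 matches), Penk, Crabp1, Papss2 and Notch1. Penk has its match at 4133701 to 4133707 of chromosome 4, minus strand, and Crabp1 at 54772944 to 54772950 of chromosome 9. The 5 largest falls with a miR-340-5p match were those of Pkp1 (-3.40), Fam19a1 (-3.18), the urea transporter gene Slc14a1 (-2.98), Tril (-2.84) and Tmem119 (-2.74), of which Pkp1 and Slc14a1 also have a miR-449a match. The strand setting of the counting is not given in the sources used here, and exons of Notch1, Penk, Kcnk3, Npr3, Ctgf, Iqcd, Ccnd1, Ccne2, Cdk4, Cdk6, E2f5, Kras, Cdkn1a and Mpc1 overlap those of annotated genes on the opposite strand. The same holds for Nusap1, Tk1, Ccnd3, Des, Neb, Tpi1, Slc2a1, Atp5f1, Got2, Timp3, Twist2, Tnc, Nefl, Eif2ak2, Rpl31, Rps2, Gas1, Ezh2, Jak1, Dll1, Smarca2, Pbrm1, Hdac4, Tagln and Tril, and Top2a, Col3a1, Rps2, Rpl18a and Numbl overlap a gene on their own strand, so counts of these genes may include reads of their neighbours. Aldoa has more than 1 annotated gene under its symbol, and its overlaps were not examined.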

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

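The tests on transfected replicate 4 by slope and by GC content and length were chosen only after the result was seen, and the genes Saa3, Cxcl1 and Cxcl5 were grouped after their values were seen.

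Among 320 groups of 4 libraries, 17 held a library far from the other 3, by a gap to the nearest that passed Dixon's 95% critical value as a share of the group's range, where chance gives about 1 in 20, or 16. Each of transfected replicates 1, 3 and 4 and vehicle replicate 1 was the distant library in 3 of them, vehicle replicates 2 and 4 in 2 each, and vehicle replicate 3 in 1. In vehicle, Papss2 was at 16.7 CPM in replicate 4 (9.64 to 10.8 in the other 3), Ccnd1 at 2350 in replicate 2 (2060 to 2104), Cdk4 at 188 in replicate 1 (228 to 235) and Ncam1 at 743 in replicate 1 (679 to 688). Also in vehicle, Idh3g was at 58.2 CPM in replicate 4 (47.9 to 48.7), Igfbp3 at 100 in replicate 3 (74.5 to 77.1), Akt3 at 83.6 in replicate 2 (64.6 to 67.3) and Cd68 at 7.56 in replicate 1 (9.65 to 9.9). After transfection, Mpc2 was at 47.2 CPM in replicate 3 (37.1 to 38.5), Slc16a1 at 166 in replicate 1 (132 to 137), Got2 at 52.6 in replicate 4 (46.5 to 46.8) and Pdk1 at 45.8 in replicate 1 (56.3 to 57.7). Psen1 was at 80 CPM in transfected replicate 3 (73.1 to 74.1), Ccp110 at 6.07 in replicate 4 (10.7 to 11.3) and Rpl27 at 571 in replicate 4 (413 to 420). Tmem119 was at 0 in transfected replicate 1, which allows up to 1.26 CPM, and at 4.3 to 4.38 in the other 3. The total count of transfected replicate 3 was 5963473, against 2405517 to 2926898 in the other 3.

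Transfected replicate 4 lay apart from the other 3 transfected libraries, with 459 of 10923 genes at least 2-fold from their mean, against 316, 234 and 103 for replicates 1 to 3. A weaker or stronger response is argued against by the slope of its fold changes on those of the other 3, which was 0.961. A length-dependent loss such as RNA degradation is argued against by Spearman's rho of its deviation with transcript length (-0.074, across genes, which are not independent). GC content and length explained 10.8% of the variance of its deviation, against 9.5%, 1.1% and 4% in the other 3, so they were not the whole cause, although rho with GC content was 0.274 there and -0.216 to -0.011 elsewhere. The design gives no biological explanation and none was tested, and a difference in handling stays open.

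The genes Saa3 (log2 fold change 6.34), Cxcl1 (2.58) and Cxcl5 (2.83) rose after transfection. A large gain of macrophages after transfection is argued against by the summed CPM of 15 macrophage markers, which was 1.21 times that of vehicle. The most abundant marker, Lyz2, was at 30.7 and 36.8 CPM. This ratio does not test the part of any macrophages present in both groups. An innate response to transfected RNA cannot be told apart from an effect of the microRNAs, since vehicle got no control RNA. The median log2 fold change of the interferon response genes was 0.124, with members moving both ways.

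Of the 35 splits of the 8 libraries into 4 and 4, only the real one (1 of 35) gave as many changed genes (5283, highest other 0). The same held for 2-fold changed genes (1596, highest other 0). Every other split mixes the 2 groups, so their difference widens the spread within each part and few calls can arise. With 35 splits no share under 1 of 35 is possible, so these counts do not by themselves exclude chance. The miR-449a coefficient was the largest in size in the real split (1 of 35, -0.279, highest other 0.14 in size). The other splits keep only part of the real contrast or none of it. The real split was therefore favoured in advance, and its rank does not by itself exclude chance. The coefficient of miR-340-5p was also the largest in size in the real split, by a small margin (1 of 35, -0.027, highest other 0.025 in size). That margin does not by itself show an effect of its sites, and a share of 0.0875 of the heptamers lay as low. As many called lists as the real 12 were given by 3 of 35 splits (highest other 12). Splits that exchange 1 or 3 libraries keep part of the real contrast, so this share does not decide on chance. Those splits gave 6 to 12 lists, and splits exchanging 2 libraries between the groups gave at most 4 (median 0).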

How the results depend on the processing

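The count of genes changed stayed within 1.5 times 5283 under every alternative run, from 4682 (without vehicle replicate 4) to 5845 (without transfected replicate 4), with 47.3% to 50.4% of them higher. The count of genes changed at least 2-fold ran from 1573 (without vehicle replicate 4) to 2178 (no filter on low counts), and from 1573 to 1795 with 1 library left out. The median log2 fold change was 0.006 in the main analysis and ran from -0.022 (without Yam1 and the mitochondrially encoded genes) to 0.014 (DESeq2 Wald test). The former, an alternative chosen after seeing the data, gave 5299 genes, 1607 of them 2-fold, and 12 lists. The 12 called lists became 4 with an estimated correlation, where the cause was not tested, and 22 by fry, which does not compare a list with other genes. The filter of at least 1 CPM in 4 libraries, which kept 12996 genes against 11023, called 13, the added list being the multiciliated cell programme, of which it let in 8 members against 4 (camera adjusted p = 0.0383), and leaving out a library gave 11 to 12. The miR-449a coefficient ran from -0.18 (coding sequence) to -0.342 (8mer) and kept its call. That of miR-340-5p passed the threshold with the hexamer (-0.057) and turned positive in the coding sequence (0.029), and the causes were not tested. With no adjustment for 3' UTR length and GC content it was -0.061, against -0.027 in the main analysis, with a share of 0.072 of the heptamers as low, and it ran from -0.033 to -0.02 with a library left out. Of 143 called named genes, 139 kept the call in all 16 alternatives; Myog, Rpl27, C1qa and Mrc1 lost it in some, Cdkn1a, Slbp, Cd68 and Lyz2 gained it in some, and 0 of 2463 pairs of gene and alternative reversed. Myog and Mrc1 were at a few CPM, and the part of read depth in their lost calls was not tested.

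With the replicate number as a block (replicate block), 5263 genes changed (2606 higher, 2657 lower), and 12 lists were called. The numbers did not pair the libraries, since same-numbered libraries correlated at 0.01 to 0.053 in their deviations, and 2 of the 4 transfected and 2 of the 4 vehicle libraries correlated best with their own number. Among the named genes, the calls of Rpl27, C1qa and Mrc1 were lost with the block.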

Other observations

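The lists of V-ATPase, lysosomal and cilium genes were picked by symbol after some of their members' values were seen, so their tests describe these data only. Their camera p-values were adjusted over these added lists only, apart from the lists fixed in advance. The adjusted values are therefore not comparable in size with those of the fixed lists. The test of cilium genes at a mean of at least 20 CPM was chosen only after the result was seen, because the filter planned for it kept more genes (12996) than the main analysis (11023) and decides nothing. Exons of Ift88, Pih1d2, Cfap97, Atp6v0b, Atp6v1g2, Npc1, Ostm1, Ddit3, Ncam1, Akt3 and Slbp overlap those of annotated genes on the opposite strand, so their counts are uncertain while the strand setting is unknown. The rank of the let-7 heptamer was noticed after its values were seen.

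Subunits of the V-ATPase, the proton pump that acidifies lysosomes and endosomes, were higher after transfection. Of 19 tested, 16 rose and 0 fell, the same adjusted over the list alone (median log2 fold change 0.95, limma camera adjusted p = 1.60e-07, and adjusted p = 0.0204 with an estimated correlation). Atp6v1d rose from 184 ± 8.25 to 502 ± 34.4 CPM (SD, n = 4 in each group), and Atp6v1a from 349 ± 18.7 to 971 ± 115 CPM. Atp6v1c1 (log2 fold change 1.26) and Atp6v0b (1.37) also rose, while Atp6v1g2 did not pass the test (-0.75). Of 58 genes of lysosomal enzymes and membrane proteins 26 rose and 5 fell, 27 and 5 adjusted over the list alone (median 0.29, camera adjusted p = 3.73e-04, and adjusted p = 0.0204 with an estimated correlation). The cholesterol transporter gene Npc1 rose from 105 ± 6.52 to 270 ± 16.8 CPM, and Neu1 (1.57), Ostm1 (1.90) and Gla (1.18) rose, while Scarb2 (-1.39) fell.

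Among 13 tested histone cluster genes 7 rose and 5 fell (median log2 fold change 0.74). The libraries hold polyadenylated RNA, so transcripts of these genes without a poly(A) tail were not measured. Ddit3 and Hmox1, chosen after their values were seen, rose from 110 ± 15.9 to 399 ± 53.8 CPM and from 68.8 ± 10.6 to 212 ± 64.4 CPM. Trp53 was at 3.27 ± 1.26 CPM in vehicle and 2.75 ± 0.86 CPM after transfection, with 45 and 40 counts over the 4 libraries.

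Cilium genes were higher, with 28 of 52 tested rising and 3 falling (median log2 fold change 0.54, limma camera adjusted p = 2.43e-08, and adjusted p = 0.0012 with an estimated correlation), among them Ift74 (321 ± 25.5 to 937 ± 109.5 CPM), Wdr35 (1.84), Ift88 (2.47) and Pih1d2 (3.06), with Cfap97 (-0.59) lower. To test imprecise folds of low-count genes, the 18 cilium genes with a mean of at least 20 CPM over all 8 libraries were taken. Of these, 12 rose and 1 fell (median 0.68, camera adjusted p = 1.18e-04, and adjusted p = 0.0585 with an estimated correlation, which loses the call). This argues against imprecise folds for these 18 genes. It does not decide for the list, which was picked after values were seen, and a mean over both groups lets in genes through the group where they are high. To test a general rise of genes little expressed in vehicle, 10000 random lists were matched on vehicle expression. Their medians lay between -0.104 and 0.335 in 95% of draws, below the 0.54 of the cilium genes. Since the cilium list was picked after some members' values were seen, part of this excess may reflect the choice, and it does not decide. Loss of Ccp110, which caps centrioles, is argued against as the cause because it was called higher (1.33), the opposite of what this needs, although the bound set beforehand had asked for no call.

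A hypothesis is that the transfected microRNAs competed with endogenous ones, so that genes with sites for abundant endogenous microRNAs rose. The median coefficient of the heptamers of 12 such families was 0.037, at the 99.65th percentile of 10000 random sets matched on site frequency and the 99.66th of sets also matched on GC content, and all 12 were positive. That of let-7 (CTACCTC) was 0.113, the highest of all heptamers. These values are consistent with competition, which the abundance of the microRNAs, not measured here, would have to bear out.

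A further hypothesis was that sites for both microRNAs in a 3' UTR act more than additively on the log scale. The interaction coefficient was 0.149, at the 92.4th percentile of 1000 permutations of the miR-340-5p site among genes of like UTR length, whose median was 0.0823 (SD 0.0458). A more than additive effect would place it below most permutations, so it argues against this.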
